A study of Mus musculus with 16 samples.

How the data were processed

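RNA of macrophages sorted from perigonadal adipose tissue was measured on 16 Affymetrix mouse whole-genome expression arrays of one design, 4 for each of 4 groups, after 2 rounds of amplification. The groups were FB cells, positive for the Adgre1-encoded macrophage antigen and CD11b and negative for CD11c, and FBC cells, positive for all 3, of lean (Lep +/+) and obese (Lep ob/ob) mice, as the labels give them, and no column was left out. The values deposited by the authors are probe set intensity on a linear scale, made with Affymetrix Expression Console per the submitters' processing notes. The 2% trimmed mean was 250 on every array. The summarization method, the software version and the genome build are not given in the sources used here, and the values hold no detection calls.

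The values were taken as log2(intensity + 16). Because the medians of the arrays differed by more than 0.1, the arrays were quantile-normalized. Of 45101 probe sets, 64 were controls, 34945 carried 1 gene symbol, 932 several and 9147 none. Probe sets with several symbols or none were not used here. Symbols came from the platform annotation; the gene IDs of 34741 single-symbol probe sets were in a RefSeq gene table, and 0 symbols were renamed. Each of 18193 genes was represented by its single-symbol probe set with the highest mean. The 11908 genes above the array median on at least 4 of the 16 arrays were tested.

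One limma model of the 4 groups gave 5 comparisons: obese against lean in FB and in FBC, FBC against FB in lean and in obese mice, and the difference of the obesity effect between FBC and FB. Moderated statistics came from lmFit and eBayes, with 12 residual and 16.5 total degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Fixed lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and 34 of 35 lists had the 5 or more tested genes needed. A list score is the mean centred log2 value of its tested genes on an array. The correlation across arrays was tested with 100000 permutations, two-sided. The tools were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9. The comparisons, lists, naming rule and most of the other settings were chosen before the data were examined.

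Named genes were, per comparison, the 8 highest and 8 lowest log2 changes among called genes whose groups did not overlap, clone and model symbols left out, and 5 and 5 for the interaction. To these were added up to 3 called members with the largest change from each called list, and always from the lysosome, lipid uptake, M1 and M2 lists, and the 3 sort markers; genes from lists were in part left out for length. Other single-symbol probe sets existed for 108 of the entries made by this rule, and 1 of these, Car3 in FB, had a probe set called the other way. No other probe set of Efr3b and Dcn in FB, and of Marco and Cpt2 in obese FBC against FB, moved in the same direction. Some but not all did for Sox4, Vldlr, Fscn1 and Cxcl12 in FB, for Sox4, Car3, Cd40, Vcan and Atf4 in FBC, for Fscn1 and Vcan in lean and obese FBC against FB, for Socs2 in obese FBC against FB, and for Pkp2 and Plcb1 in the interaction. The Cd209, Ear and Rnase2a genes belong to multigene families whose members one probe set may not separate. The lower group of several named genes, among them Gpr176, Efr3b, Rnase2a, Sult1e1, Aff3, Klhl13, Cd34, Upk3b and Ces1d in FB, lay below the array median, near background, so their changes are imprecise in size.

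Whether the numbers of the arrays pair them by mouse was checked by the correlation of residuals. Arrays of lean FB and lean FBC with the same number correlated at 0.135, 0.231, 0.299 and 0.595, all above the limit of 0.1, and lean FB array 1 matched number 3 best. In obese mice the correlations were 0.31, 0.033, -0.03 and -0.137. The main model has no pairing, and the blocked value stands beside the lean result. The model was tested on simulated data of the same design, with 100 genes changed by a log2 of 1 and 100 by 2. It recovered 58 and 96 in FB, 67 and 96 in FBC, 52 and 97 in lean, 69 and 95 in obese and 26 and 69 in the interaction, with 5, 7, 13, 8 and 5 false calls. The simulated noise was independent between genes and equally wide on all arrays, so these numbers need not hold for the real arrays. The number of arrays limits the precision, and p-values measure the spread between arrays, which stand for mice where each array came from its own mouse.

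The other settings chosen then were no filter and a stricter filter (60th percentile), the mean of a gene's probe sets, all probe sets singly, no quantile normalization, median centring, cyclic loess, a pseudocount of 1, eBayes with trend and robust settings, array weights, only the groups compared, a replicate block, mouse as a random block, a 2-fold minimum, an estimated correlation and each array left out in turn. The normalization alternatives kept the genes and probe sets of the main setting. After the data were seen, the log2 actin 3'/5' ratio as a covariate and the omission of the 3 arrays with a ratio above 40 were added.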

Results

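The series profiled macrophages sorted from perigonadal adipose tissue of lean (Lep +/+) and obese leptin-deficient (Lep ob/ob) C57BL/6J mice aged 12 to 14 weeks. Mice without functional leptin overeat and become obese. Cells were sorted by 3 surface markers, the macrophage antigen encoded by Adgre1, CD11b encoded by Itgam, and CD11c encoded by Itgax. FB macrophages carry the first and CD11b but not CD11c, and FBC macrophages carry all 3. RNA of each sorted sample, amplified in 2 rounds, was hybridised to its own array, giving 4 arrays each of lean FB, lean FBC, obese FB and obese FBC. The trimmed mean signal was 250 on each of the 16 arrays. The median log2 value ranged from 5.69 to 6.06 before normalization, and 11908 genes were bright enough to test. The number of arrays limits the precision of every value below, and p-values measure the spread between these arrays. Changes are log2 differences ± SE from limma, on the log2(intensity + 16) scale, which understates the change of dim genes. Levels are means ± SD over the 4 arrays of a group.

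The sort markers were read first, since they check the labels. Itgax was at 8.80 ± 0.21 in lean FB, 10.29 ± 0.49 in lean FBC, 8.78 ± 0.36 in obese FB and 10.99 ± 0.39 in obese FBC. It was higher in FBC than in FB in lean mice (1.49 ± 0.26, adjusted p = 0.0213) and in obese mice (2.21 ± 0.26, adjusted p = 0.000111), and every FBC array lay above every FB array of its genotype. Tested among all single-symbol probe sets, its adjusted p in lean mice was 0.0563. Adgre1 was between 11.94 and 13.69 on all 16 arrays, and Itgam between 6.84 and 8.39. Adgre1 rose with obesity in FBC (1.08 ± 0.23, adjusted p = 0.00668), while its FBC to FB differences did not pass in lean (-0.41 ± 0.23, adjusted p = 0.689) or obese mice (0.69 ± 0.23, adjusted p = 0.0806). Itgam passed the threshold in none of the 4 pairwise comparisons by limma, with adjusted p between 0.857 and 0.937.

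**Figure D1:**
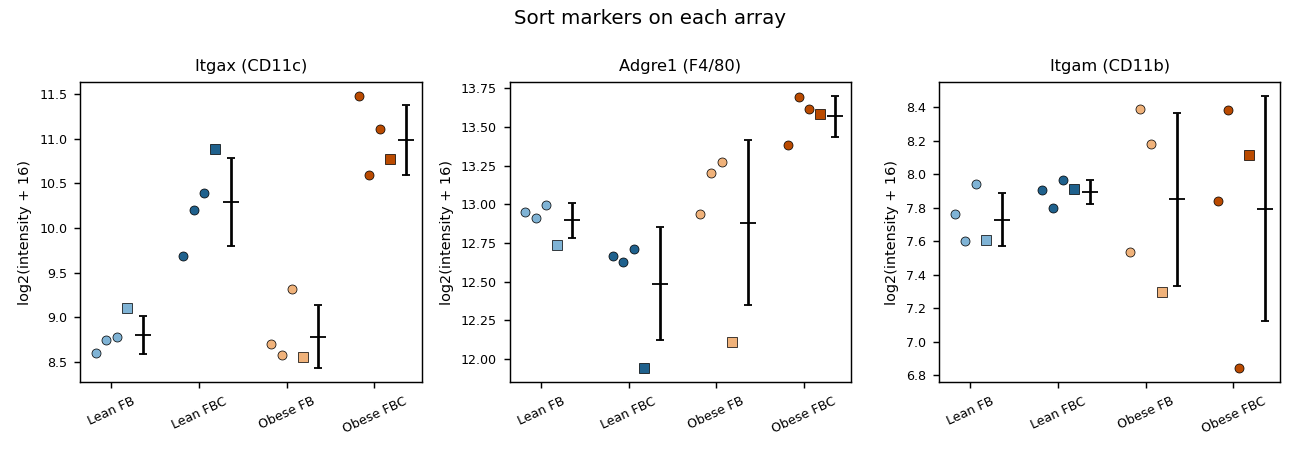
Level of the sort marker genes on each of the 16 arrays, as log2(intensity + 16), by group. Points are arrays, squares are arrays numbered 4, and bars give the mean ± SD of 4 arrays; Itgax lies at 9.69 or above on the FBC arrays and at 9.31 or below on the FB arrays.

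RNA quality differed between arrays. The ratio of the 3' to the 5' actin probe sets was 53.3 on lean FB array 4, 48.0 on lean FBC array 4 and 45.0 on obese FB array 4, and between 1.15 and 10.9 on the others. The log2 of this ratio followed the second principal component, which held 24.0% of the variance (n = 16, Pearson r = -0.826, permutation p = 0.00012, Spearman rho = -0.709, permutation p = 0.00264). This was the 1 relation of this kind computed. Pearson r was -0.697 without the 2 arrays farthest from the median ratio and -0.424 without the 3 highest. Lean FB array 4 also had a Siglecf level of 11.98, against 7.98 to 8.53 on the other lean FB arrays; Siglecf is an eosinophil surface lectin.

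**Figure D2:**
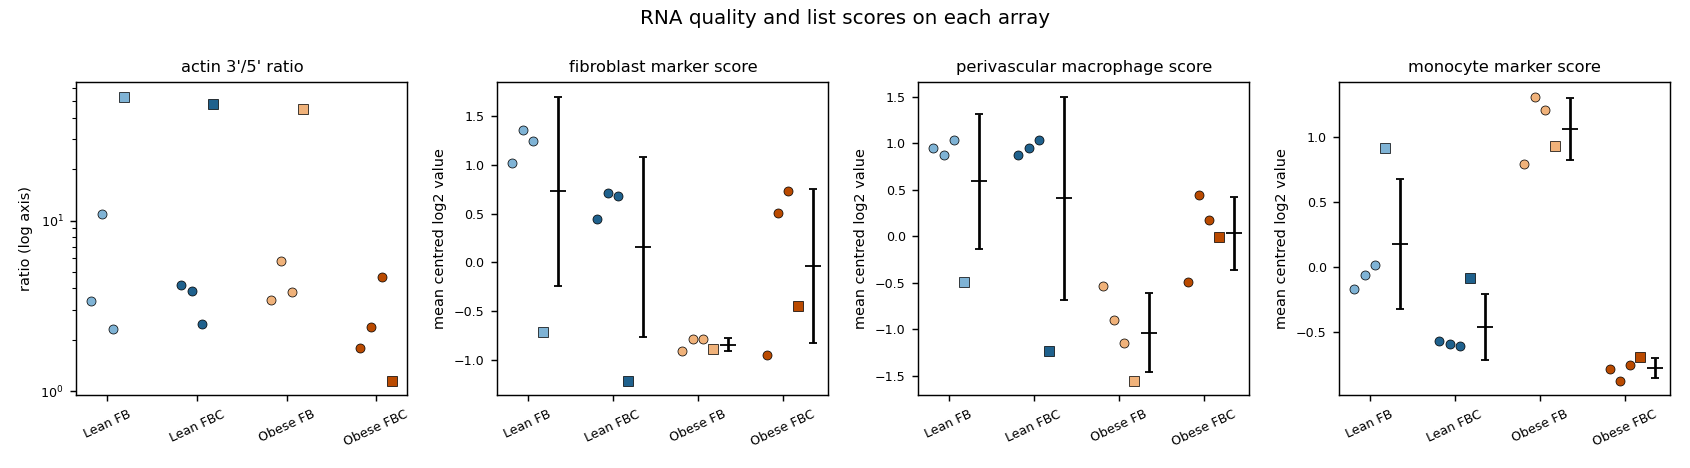
Actin 3'/5' ratio (log axis) and mean centred log2 score of the fibroblast, perivascular macrophage and monocyte lists on each of the 16 arrays, by group. Points are arrays, squares are arrays numbered 4, and bars on the 3 score panels give the mean ± SD of 4 arrays; lean FB and lean FBC arrays 4 have fibroblast scores of -0.72 and -1.22.

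The comparison of obese with lean FB macrophages asks how leptin-deficient obesity changes the cells without CD11c. The genes that fell furthest included Cd209g (-5.60 ± 0.66), Cd209f (-4.04 ± 0.64) and Cd209b (-3.90 ± 0.66), C-type lectins of resident macrophages. Also among them were the ribonuclease gene Rnase2a (-5.33 ± 0.46), the estrogen sulfotransferase Sult1e1 (-4.67 ± 0.65), Klhl13 (-4.35 ± 0.56), Aff3 (-3.90 ± 0.32) and the adipocyte carbonic anhydrase Car3 (-4.33 ± 0.50). Those that rose furthest included the ubiquitin ligase Rnf128 (3.14 ± 0.27), Cd177 (2.61 ± 0.42), a surface glycoprotein of neutrophils, and the transcription factor Sox4 (2.44 ± 0.37). The receptor Gpr176 (2.42 ± 0.28), the collagen-degrading cathepsin K, Ctsk (2.37 ± 0.46), carboxypeptidase E, Cpe (2.35 ± 0.39), Efr3b (2.18 ± 0.43) and the myeloid receptor Trem3 (2.15 ± 0.38) followed. The adjusted p of these 16 genes was at most 0.00558. In all, 701 genes changed, 216 higher and 485 lower, of which 490 by at least 2-fold, and 2403 genes had an unadjusted p under 0.05.

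Alternative activation genes, which interleukin 4 induces in macrophages, fell as a group in obese FB. The alternative activation list gave a median change of -0.53, adjusted p = 6.16e-08, and adjusted p = 0.00107 with an estimated correlation (3 higher and 11 lower adjusted over the list alone). Of 24 tested, 2 rose and 10 fell. Retnla (-3.02 ± 0.31), Ccl17 (-2.88 ± 0.28) and Cd209d (-2.83 ± 0.40) fell, and Chil3 (1.74 ± 0.45), a chitinase-like protein also listed as a monocyte gene, rose. Interferon-stimulated genes fell too, with 9 of 25 past the threshold, among them the antiviral genes Ifit1 (-2.31 ± 0.38), Oasl1 (-1.74 ± 0.47) and Oas2 (-1.37 ± 0.27). The interferon list gave a median change of -0.72, adjusted p = 6.16e-08, and adjusted p = 0.102 with an estimated correlation (0 higher and 12 lower adjusted over the list alone). Classic activation genes fell, 4 of 23, including the cytokine subunit Il12b (-2.24 ± 0.49) and the chemokines Cxcl11 (-2.09 ± 0.41) and Ccl5 (-1.71 ± 0.43). The classic activation list gave a median change of -0.55, adjusted p = 0.000584, and adjusted p = 0.166 with an estimated correlation (0 higher and 8 lower adjusted over the list alone). Of the chemokine list 1 rose and 8 fell of 29, with the lymphoid chemokine Cxcl13 (-3.53 ± 0.96), Ccl17 and Cxcl12 (-2.68 ± 0.46) lowest. The chemokine list gave a median change of -0.61, adjusted p = 4.51e-05, and adjusted p = 0.119 with an estimated correlation (1 higher and 9 lower adjusted over the list alone). Dendritic cell markers fell, 8 of 20, with Ccl22 (-2.48 ± 0.36) and the actin-bundling gene Fscn1 (-2.23 ± 0.29). The dendritic cell list gave a median change of -0.76, adjusted p = 8.1e-08, and adjusted p = 0.102 with an estimated correlation (1 higher and 10 lower adjusted over the list alone). MHC class II genes fell, 2 of 15, namely H2-DMb2 (-2.08 ± 0.34) and H2-DMa (-0.95 ± 0.21), which load peptides. The MHC class II list gave a median change of -0.34, adjusted p = 0.00115, and adjusted p = 0.187 with an estimated correlation (0 higher and 2 lower adjusted over the list alone).

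Perivascular macrophage genes fell in obese FB, 8 of 23, led by the Cd209 genes above; the perivascular score of lean FB array 4 was -0.49 against at least 0.88 on the other lean FB arrays. The perivascular list gave a median change of -1.27, adjusted p = 8.84e-09, and adjusted p = 0.257 with an estimated correlation (0 higher and 11 lower adjusted over the list alone). Preadipocyte and fibroblast markers fell beside them, 8 of 20, including Dpep1 (-3.03 ± 0.69), decorin, Dcn (-2.86 ± 0.77), and Cd34 (-2.73 ± 0.65). The fibroblast list gave a median change of -1.37, adjusted p = 8.84e-09, and adjusted p = 0.221 with an estimated correlation (0 higher and 13 lower adjusted over the list alone). The fibroblast score was -0.85 ± 0.07 in obese FB and 0.73 ± 0.98 in lean FB, where array 4 stood at -0.72. Complement genes fell, 4 of 13, with C2 (-2.78 ± 0.53) and the C1 inhibitor Serping1 (-2.67 ± 0.71). The complement list gave a median change of -0.69, adjusted p = 0.000678, and adjusted p = 0.294 with an estimated correlation (0 higher and 5 lower adjusted over the list alone). The complement score of lean FB array 4 was -0.57, within the obese FB range of -0.95 to -0.42, against at least 0.59 on the other lean FB arrays. Mesothelial and epithelial markers fell, 4 of 13, led by Upk3b (-3.31 ± 0.70). The mesothelial list gave a median change of -0.89, adjusted p = 5.87e-05, and adjusted p = 0.19 with an estimated correlation (0 higher and 6 lower adjusted over the list alone). Adipocyte markers fell, 4 of 13, led by Car3. The adipocyte list gave a median change of -0.27, adjusted p = 0.0119, and adjusted p = 0.251 with an estimated correlation (1 higher and 6 lower adjusted over the list alone). The adipocyte score of lean FB array 4 was -0.32, against at least 0.40 on the others. The matrix list shifted down with 1 member higher and 1 lower of 24. The matrix list gave a median change of -0.81, adjusted p = 0.01, and adjusted p = 0.338 with an estimated correlation (3 higher and 10 lower adjusted over the list alone). The matrix score of that array was -0.49, against at least 0.34.

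Monocyte markers rose in obese FB, 4 of 15, including Treml4 (2.35 ± 0.58), haptoglobin, Hp (1.88 ± 0.35), and Chil3; the monocyte score of lean FB array 4 was 0.91 against at most 0.01 on the other lean FB arrays. The monocyte list gave a median change of 0.88, adjusted p = 2.01e-05, and adjusted p = 0.156 with an estimated correlation (8 higher and 0 lower adjusted over the list alone). Lipid-associated macrophage genes rose, 5 of 26, with Gpnmb (1.35 ± 0.37) and the fatty acid carrier Fabp5 (0.73 ± 0.18). The lipid-associated macrophage list gave a median change of 0.30, adjusted p = 0.000246, and adjusted p = 0.257 with an estimated correlation (5 higher and 0 lower adjusted over the list alone). The lean and obese FB arrays overlapped for Oasl1, Treml4, Hp, Atp6v1h and Gpnmb. Lysosome genes shifted up, 4 higher and 1 lower of 45, and the proton pump subunits moved apart, Atp6v0d2 (1.71 ± 0.35) up and Atp6v1h (-1.73 ± 0.48) down. The lysosome list gave a median change of 0.15, adjusted p = 0.0288, and adjusted p = 0.495 with an estimated correlation (4 higher and 1 lower adjusted over the list alone). The lipid uptake list had 6 higher and 2 lower of 29 and no call (adjusted p = 0.101, 8 higher and 4 lower adjusted over the list alone), with Apoc2 (1.77 ± 0.32) up and Vldlr (-2.41 ± 0.64) and Ces1d (-1.68 ± 0.28) down.

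Other lists shifted in obese FB with few members past the threshold. The list of 30 cell cycle genes shifted up, with 1 higher and 0 lower past the threshold. The cell cycle list gave a median change of 0.46, adjusted p = 0.000246, and adjusted p = 0.427 with an estimated correlation (0 higher and 0 lower adjusted over the list alone). The list of 34 oxidative phosphorylation genes shifted up too, though by limma no single gene passed the threshold. The oxidative phosphorylation list gave a median change of 0.23, adjusted p = 0.00628, and adjusted p = 0.343 with an estimated correlation (0 higher and 0 lower adjusted over the list alone). The list of 22 unfolded protein response genes shifted down, though by limma no single gene passed the threshold. The unfolded protein list gave a median change of -0.15, adjusted p = 0.0254, and adjusted p = 0.119 with an estimated correlation (0 higher and 0 lower adjusted over the list alone). The list of 27 immediate early and dissociation stress genes shifted down, with 0 higher and 1 lower past the threshold. The immediate early list gave a median change of -0.30, adjusted p = 0.00402, and adjusted p = 0.263 with an estimated correlation (0 higher and 3 lower adjusted over the list alone). The list of 6 mast cell markers was called lower, though by limma no single gene passed the threshold. The mast cell list gave a median change of -0.48, adjusted p = 0.0163, and adjusted p = 0.119 with an estimated correlation (0 higher and 0 lower adjusted over the list alone). The list of 9 B cell markers was called lower, with 0 higher and 1 lower past the threshold. The B cell list gave a median change of -0.62, adjusted p = 0.00889, and adjusted p = 0.142 with an estimated correlation (1 higher and 4 lower adjusted over the list alone). The list of 13 T and NK cell markers was called lower, with 0 higher and 4 lower past the threshold. The T and NK cell list gave a median change of -0.34, adjusted p = 0.00308, and adjusted p = 0.157 with an estimated correlation (0 higher and 5 lower adjusted over the list alone).

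**Figure D3:**
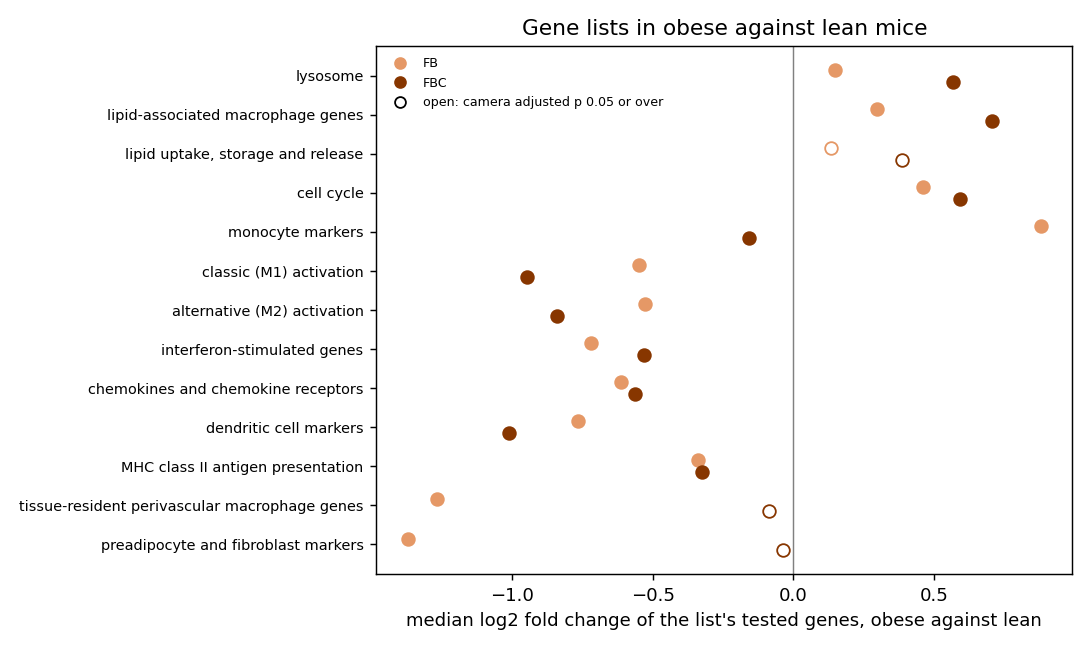
Median log2 fold change of the tested genes of 13 lists in obese against lean FB (light) and FBC (dark). Filled points have a camera adjusted p under 0.05 at the preset correlation. The fibroblast list lies at -1.37 in FB and -0.04 (open) in FBC. Without the 3 arrays of high actin ratio, FBC gives -0.43 (adjusted p = 0.00262, 0.446 with an estimated correlation).

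The FB count rested on few arrays. It was 2022 without the 3 arrays of high actin ratio, 1159 with the actin ratio as a covariate, 3987 with array weights (2097 higher and 1890 lower), 401, 333, 336 and 1501 without lean FB arrays 1, 2, 3 and 4, and 444 and 395 without obese FB arrays 2 and 3. Gene calls ended on leaving out 1 array, with the highest adjusted p each reached, without lean FB array 1 those of Cxcl13 (0.125), without lean FB array 2 those of Ccl5 (0.0837), Cd34 (0.0772), Chil3 (0.117), Dcn (0.123), Dpep1 (0.0663), Oasl1 (0.126), Serping1 (0.125), Treml4 (0.0914) and Vldlr (0.115), without lean FB array 3 those of H2-DMa (0.0611), without obese FB array 3 those of Atp6v1h (0.139), Fabp5 (0.0813) and Gpnmb (0.13), and other settings ended those of Dcn, Oasl1, Il12b, Ccl5, Atp6v1h, Vldlr, Gpnmb, Fabp5, Fscn1 and Cxcl13 (adjusted p 0.0501 to 0.18). List calls ended, with their highest adjusted p, for lysosome (0.19 without lean FB array 4 and 0.103 under another setting), unfolded protein response (0.0793 under another setting) and B cell markers (0.0766 under another setting). Medians moved by over 1.5 times without the 3 arrays of high actin ratio for the unfolded protein list (-0.24).

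The same question in FBC macrophages, the cells with CD11c, gave a larger set. Genes with the greatest rise were Efr3b (4.11 ± 0.43), Cpe (3.92 ± 0.39), the serotonin receptor Htr2b (3.61 ± 0.31) and Ctsk (3.51 ± 0.46). Next came the lysosomal membrane glycoprotein Gpnmb (3.24 ± 0.37), the kinase Cdk18 (3.13 ± 0.30), Sox4 (3.11 ± 0.37) and Fgf13 (3.09 ± 0.28). Those with the greatest fall were Rnase2a (-4.48 ± 0.46), the plasminogen activator inhibitor Serpinb2 (-4.16 ± 0.39), the secreted phospholipase Pla2g2d (-3.90 ± 0.62) and Cd209g (-3.86 ± 0.66). Smaller falls were those of Sult1e1 (-3.78 ± 0.65), Aff3 (-3.69 ± 0.32), Car3 (-3.63 ± 0.50) and Flrt3 (-3.60 ± 0.29). The adjusted p of these 16 genes was at most 0.00122. In all, 1675 genes changed, 967 higher and 708 lower, 811 of them by at least 2-fold (397 higher and 414 lower), and 3445 had an unadjusted p under 0.05.

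Lysosome genes rose in obese FBC, 17 higher and 1 lower of 45. The lysosome list gave a median change of 0.57, adjusted p = 1.74e-09, and adjusted p = 0.109 with an estimated correlation (23 higher and 1 lower adjusted over the list alone). Gusb (1.99 ± 0.16), a glucuronidase, and the proton pump subunit Atp6v0d2 (2.5 ± 0.35) rose with Ctsk. Lipid-associated macrophage genes rose, 9 of 26, with Gpnmb, Atp6v0d2 and Pld3 (2.12 ± 0.49) highest. The lipid-associated macrophage list gave a median change of 0.70, adjusted p = 8.15e-07, and adjusted p = 0.178 with an estimated correlation (16 higher and 0 lower adjusted over the list alone). The lipid uptake list had 10 higher and 2 lower of 29 and no call (adjusted p = 0.0674, 12 higher and 3 lower adjusted over the list alone): the cholesterol ester hydrolase Nceh1 (2.04 ± 0.27) and the lysosomal phospholipase Pla2g15 (1.64 ± 0.39) rose, and the oxidised lipoprotein receptor Olr1 (-2.94 ± 0.51) fell. Phagocytosis and efferocytosis receptors rose, 8 higher and 2 lower of 24, with the phosphatidylserine bridge Mfge8 (2.15 ± 0.29) up and the phosphatidylserine receptor Timd4 (-2.79 ± 0.36) and Cd209f (-2.92 ± 0.64) down, the last with overlapping arrays. The phagocytosis list gave a median change of 0.53, adjusted p = 0.0155, and adjusted p = 0.109 with an estimated correlation (10 higher and 3 lower adjusted over the list alone). The phagocytosis score of lean FBC array 4 was -0.51, against at least -0.09 on the other lean FBC arrays, and its cell cycle score 0.62, against at most -0.03. Cell cycle genes rose, 5 of 30, namely the mitotic genes Birc5 (1.51 ± 0.23), Prc1 (1.21 ± 0.33) and Cdk1 (1.16 ± 0.32) and 2 more. The cell cycle list gave a median change of 0.59, adjusted p = 0.000928, and adjusted p = 0.529 with an estimated correlation (5 higher and 0 lower adjusted over the list alone).

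Activation genes of both kinds fell in obese FBC. Classic activation genes fell, 12 of 23, with the itaconate-producing enzyme Acod1 (-3.23 ± 0.48), Il6 (-3.06 ± 0.31) and the costimulatory gene Cd80 (-2.49 ± 0.35) lowest. The classic activation list gave a median change of -0.95, adjusted p = 1.74e-09, and adjusted p = 0.0421 with an estimated correlation (0 higher and 13 lower adjusted over the list alone). Alternative activation genes fell, 1 higher and 12 lower of 24, with Ccl17 (-3.34 ± 0.28), Retnla (-3.11 ± 0.31) and Cd209d (-2.62 ± 0.40). The alternative activation list gave a median change of -0.84, adjusted p = 2.43e-07, and adjusted p = 0.00153 with an estimated correlation (3 higher and 12 lower adjusted over the list alone). Dendritic cell markers fell, 1 higher and 10 lower of 20, with Cd24a (-2.85 ± 0.57) and Cd1d1 (-2.57 ± 0.22). The dendritic cell list gave a median change of -1.01, adjusted p = 6.25e-07, and adjusted p = 0.0682 with an estimated correlation (3 higher and 12 lower adjusted over the list alone). Interferon-stimulated genes fell, 9 of 25, with Ifit1 (-2.03 ± 0.38), Gbp3 (-1.96 ± 0.23) and the RNA sensor Ifih1 (-1.63 ± 0.28). The interferon list gave a median change of -0.53, adjusted p = 8.15e-07, and adjusted p = 0.0838 with an estimated correlation (0 higher and 9 lower adjusted over the list alone). The chemokine list had 1 higher and 9 lower of 29, with the neutrophil attractant Cxcl3 (-2.59 ± 0.43) and the eosinophil attractant Ccl24 (-2.18 ± 0.40). The chemokine list gave a median change of -0.56, adjusted p = 3.36e-06, and adjusted p = 0.0682 with an estimated correlation (2 higher and 11 lower adjusted over the list alone). The MHC class II list fell, 5 of 15, with H2-DMb2 (-2.45 ± 0.34) and the costimulatory Cd40 (-1.15 ± 0.21). It gave a median change of -0.33, adjusted p = 0.00153, and adjusted p = 0.201 with an estimated correlation (1 higher and 5 lower adjusted over the list alone). Its score on lean FBC array 4 was 0.67, against 0.03 to 0.45 on the others.

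Smaller downward shifts in FBC covered monocyte markers, 5 lower of 15, with Ms4a4c (-1.53 ± 0.35), Ifitm6 (-1.20 ± 0.27) and versican, Vcan (-1.18 ± 0.33). The monocyte list gave a median change of -0.16, adjusted p = 0.0243, and adjusted p = 0.416 with an estimated correlation (0 higher and 5 lower adjusted over the list alone). The unfolded protein response list shifted down, 1 higher and 3 lower of 22, with the transcription factor Atf4 (-1.10 ± 0.17) down and asparagine synthetase, Asns (1.08 ± 0.18), up. The unfolded protein list gave a median change of -0.26, adjusted p = 0.0155, and adjusted p = 0.0682 with an estimated correlation (1 higher and 5 lower adjusted over the list alone). The list of 13 T and NK cell markers was called lower, with 1 higher and 3 lower past the threshold. The T and NK cell list gave a median change of -0.25, adjusted p = 0.046, and adjusted p = 0.363 with an estimated correlation (1 higher and 3 lower adjusted over the list alone). The list of 13 mesothelial and epithelial markers was called lower, with 0 higher and 2 lower past the threshold. The mesothelial list gave a median change of -0.26, adjusted p = 0.0243, and adjusted p = 0.475 with an estimated correlation (0 higher and 2 lower adjusted over the list alone). The list of 23 ribosomal protein genes was called lower, with 0 higher and 2 lower past the threshold. The ribosomal list gave a median change of -0.10, adjusted p = 0.046, and adjusted p = 0.416 with an estimated correlation (0 higher and 1 lower adjusted over the list alone). Fibroblast markers were not called in FBC (median log2 change -0.04, adjusted p = 0.322), and perivascular macrophage genes 1 higher and 4 lower of 23 with no call (adjusted p = 0.146, 2 higher and 4 lower adjusted over the list alone). Without the 3 arrays of high actin ratio both lists were called lower. The fibroblast median was then -0.43 with 5 members lower (adjusted p = 0.00262, and adjusted p = 0.446 with an estimated correlation), and the perivascular median -0.62 with 2 higher and 8 lower (adjusted p = 6.64e-05, and adjusted p = 0.306 with an estimated correlation). The fibroblast and perivascular scores of lean FBC array 4 were -1.22 and -1.23, against at least 0.45 and 0.88 on the other lean FBC arrays.

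**Figure D4:**
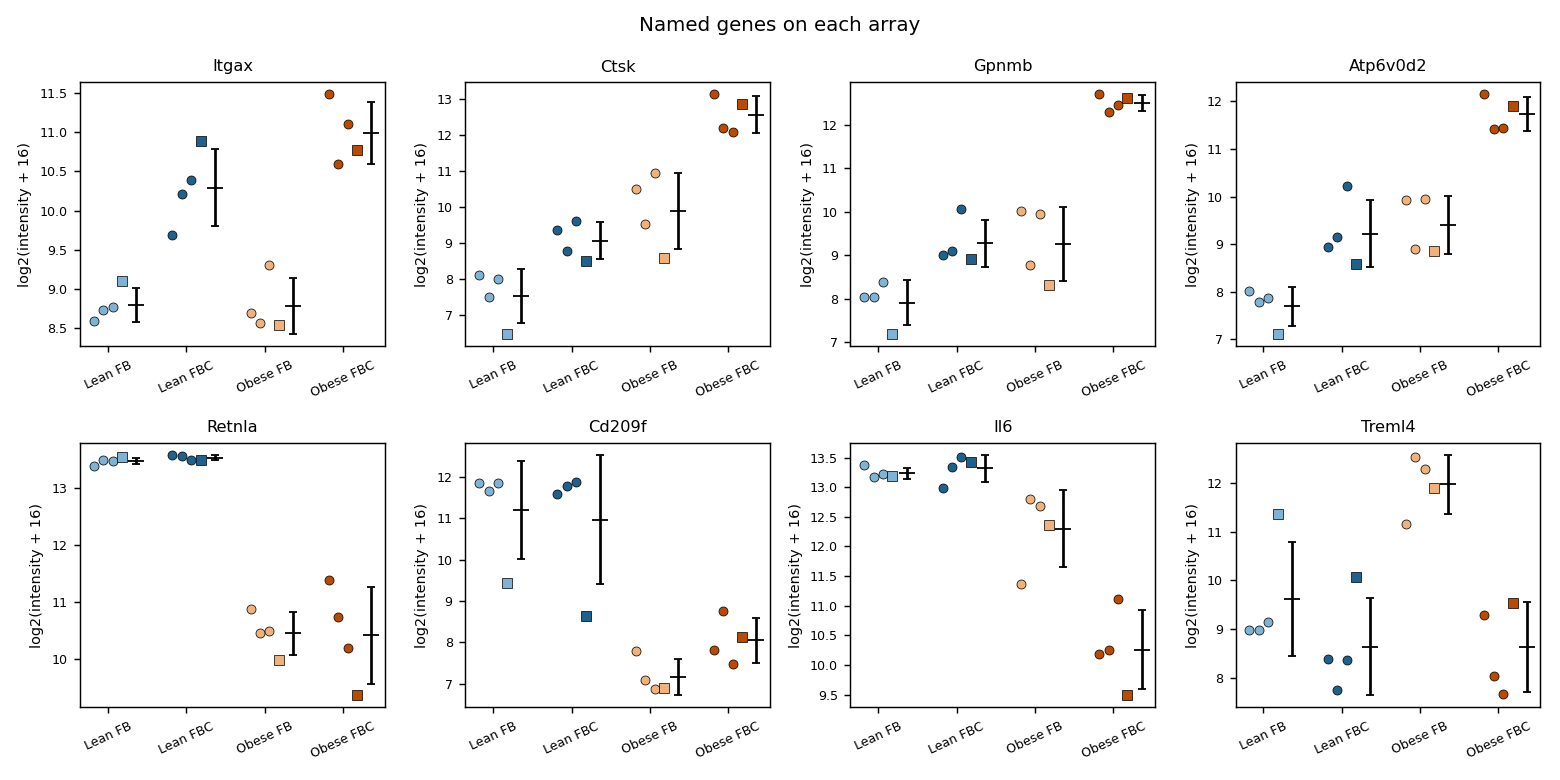
Level of 8 named genes on each of the 16 arrays, as log2(intensity + 16), by group. Points are arrays, squares are arrays numbered 4, and bars give the mean ± SD of 4 arrays; Gpnmb averages 12.50 in obese FBC and 9.27 in lean FBC, and Cd209f falls to 8.63 on lean FBC array 4.

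The FBC count was 4115 with array weights, 1040 without lean FBC array 2 and 1047 without obese FBC array 2. Gene calls ended on leaving out 1 array, with the highest adjusted p each reached, without lean FBC array 1 those of Vcan (0.075), without lean FBC array 2 those of Prc1 (0.0781), without obese FBC array 1 those of Cdk1 (0.0722), and other settings ended those of Cdk1 and Vcan (adjusted p 0.051 to 0.134). List calls ended, with their highest adjusted p, for ribosomal proteins (0.133 without lean FBC array 3 and 0.0991 under another setting), monocyte markers (0.0675 without lean FBC array 4 and 0.131 under another setting), T and NK cell markers (0.13 without lean FBC array 4 and 0.154 under another setting), mesothelial markers (0.135 without obese FBC array 4 and 0.35 under another setting) and phagocytosis receptors (0.065 under another setting). Medians moved by over 1.5 times without the 3 arrays of high actin ratio for the MHC class II list (-0.175), the phagocytosis list (0.31), the T and NK cell list (-0.04) and the mesothelial list (-0.52).

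Genes that changed with obesity in FB and in FBC were compared. Of the changed genes, 110 were higher in both populations, against 17.5 for independent lists, and 226 were lower in both, against 28.8, while 3 changed in opposite directions. Rnase2a, Aff3, Sult1e1, Cd209g, Retnla and Ccl17 fell in both, and Ctsk, Cpe, Sox4, Efr3b, Gpnmb and Atp6v0d2 rose in both. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.517. The 2 comparisons share no array, but their arrays may come from the same mice. The shared count of 336 was 934 without the 3 arrays of high actin ratio, 530 with the actin covariate, 1704 with array weights, 213 with a 2-fold minimum, and 209 and 211 without lean FB arrays 2 and 3.

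**Figure D5:**
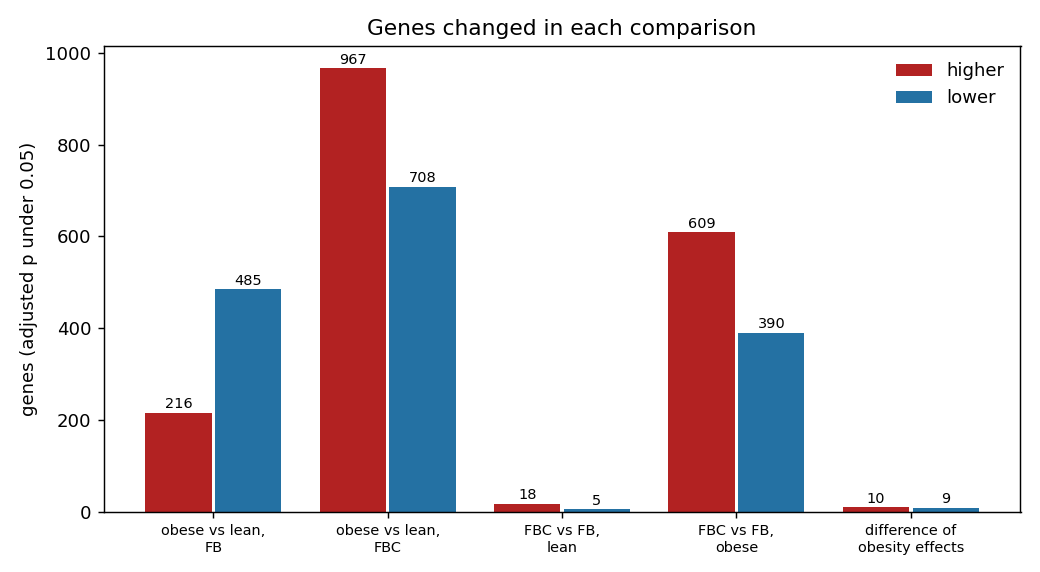
Number of genes past an adjusted p of 0.05 (limma, 11908 genes tested) in each of the 5 comparisons. Bars start at 0 and give genes higher and lower in the group named first, from 967 higher in obese FBC to 5 lower in lean FBC against FB; for the difference of obesity effects they give 10 higher and 9 lower in FBC than in FB.

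FBC and FB macrophages of lean mice were compared to find what goes with CD11c in lean fat. FBC were higher in the matrix metalloelastase Mmp12 (3.48 ± 0.55), Rnf128 (2.94 ± 0.27), the lymph node homing receptor Ccr7 (2.07 ± 0.38), and Fscn1 (2.06 ± 0.29). Also higher were Calcb (2.03 ± 0.26), the cell fusion gene Dcstamp (1.88 ± 0.34), Lhfpl2 (1.82 ± 0.27) and Mreg (1.80 ± 0.30). They were lower in the calgranulin S100a8 (-3.12 ± 0.59), Slfn4 (-1.77 ± 0.35), the myosin Myo1d (-1.74 ± 0.28), the proteoglycan Vcan (-1.73 ± 0.33) and the thrombin receptor F2r (-1.25 ± 0.23). The adjusted p of these 13 genes was at most 0.048. In all, 23 genes differed, 18 higher and 5 lower, and 976 had an unadjusted p under 0.05.

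Lipid-associated macrophage genes were higher in lean FBC, 3 of 26, including Fabp5 (1.03 ± 0.18) and Itgax, which the sort selects. The lipid-associated macrophage list gave a median change of 0.27, adjusted p = 2.69e-06, and adjusted p = 0.298 with an estimated correlation (6 higher and 0 lower adjusted over the list alone). Dendritic cell markers were higher, 2 of 20, namely Ccr7 and Fscn1. The dendritic cell list gave a median change of 0.39, adjusted p = 9.74e-09, and adjusted p = 0.0515 with an estimated correlation (5 higher and 0 lower adjusted over the list alone). Cell cycle genes were higher, 1 of 30, namely the mitotic kinase Bub1 (1.33 ± 0.25). The cell cycle list gave a median change of 0.67, adjusted p = 3.52e-14, and adjusted p = 0.298 with an estimated correlation (9 higher and 0 lower adjusted over the list alone). The cell cycle score of lean FBC array 4 was 0.62, against at most -0.03 on the other lean FBC arrays. Neutrophil markers were lower, 2 of 13, namely S100a8 and Slfn4. The neutrophil list gave a median change of -1.12, adjusted p = 4.54e-14, and adjusted p = 0.0515 with an estimated correlation (0 higher and 10 lower adjusted over the list alone). Monocyte markers were lower, 1 of 15, namely Vcan. The monocyte list gave a median change of -0.24, adjusted p = 7.39e-05, and adjusted p = 0.298 with an estimated correlation (0 higher and 4 lower adjusted over the list alone). The monocyte scores of lean FB and lean FBC arrays 4 were 0.91 and -0.09, against at most 0.01 and -0.57. The list of 34 oxidative phosphorylation genes shifted up, though by limma no single gene passed the threshold. The oxidative phosphorylation list gave a median change of 0.14, adjusted p = 0.0105, and adjusted p = 0.485 with an estimated correlation (0 higher and 0 lower adjusted over the list alone). The list of 23 ribosomal protein genes shifted up, though by limma no single gene passed the threshold. The ribosomal list gave a median change of 0.09, adjusted p = 0.049, and adjusted p = 0.474 with an estimated correlation (1 higher and 0 lower adjusted over the list alone).

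Further lists were called lower in lean FBC. The list of 25 interferon-stimulated genes shifted down, though by limma no single gene passed the threshold. The interferon list gave a median change of -0.09, adjusted p = 0.0146, and adjusted p = 0.462 with an estimated correlation (0 higher and 2 lower adjusted over the list alone). The list of 5 eosinophil markers shifted down, though by limma no single gene passed the threshold. The eosinophil list gave a median change of -1.36, adjusted p = 0.00187, and adjusted p = 0.415 with an estimated correlation (0 higher and 2 lower adjusted over the list alone). The eosinophil score was 3.27 on lean FB array 4. The list of 6 mast cell markers shifted down, though by limma no single gene passed the threshold. The mast cell list gave a median change of -0.55, adjusted p = 0.00175, and adjusted p = 0.0515 with an estimated correlation (0 higher and 2 lower adjusted over the list alone). The list of 20 fibroblast markers shifted down, though by limma no single gene passed the threshold. The fibroblast list gave a median change of -0.60, adjusted p = 0.00175, and adjusted p = 0.644 with an estimated correlation (0 higher and 0 lower adjusted over the list alone). The list of 13 mesothelial and epithelial markers shifted down, though by limma no single gene passed the threshold. The mesothelial list gave a median change of -0.33, adjusted p = 0.00504, and adjusted p = 0.462 with an estimated correlation (0 higher and 1 lower adjusted over the list alone). The lists lysosome, lipid uptake, M1 and M2 were not called (adjusted p = 0.512, 0.543, 0.496 and 0.202).

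The lean FBC to FB count was 74 with mouse as a random block and 51 with the replicate number as a block, under which Vcan (adjusted p = 0.0535) and the ribosomal list (adjusted p = 0.0611) lost their calls; median centring gave 39 higher and 3 lower, array weights 1324, the groups compared alone 9, the stricter filter 37, the actin covariate 62, omission of the 3 arrays of high actin ratio 15, and omission of lean FB array 2 or 3 or lean FBC array 2, 3 or 4 gave 8, 9, 8, 8 and 14. Gene calls ended on leaving out 1 array, with the highest adjusted p each reached, without lean FB array 2 those of Bub1 (0.113), without lean FB array 3 those of Fabp5 (0.0816), Itgax (0.0816) and Mreg (0.0775), without lean FBC array 2 those of Myo1d (0.0613), without lean FBC array 3 those of Ccr7 (0.123), F2r (0.0993), Mmp12 (0.0553), Slfn4 (0.142) and Vcan (0.129), without lean FBC array 4 those of Dcstamp (0.0892) and S100a8 (0.122), and other settings ended those of Ccr7, Fscn1, Dcstamp, Lhfpl2, Mreg, S100a8, Slfn4, Myo1d, Vcan, F2r, Itgax, Fabp5 and Bub1 (adjusted p 0.0502 to 0.328). List calls ended, with their highest adjusted p, for interferon-stimulated genes (0.258 without lean FBC array 4 and 0.434 under another setting), oxidative phosphorylation (0.138 without lean FBC array 3), ribosomal proteins (0.245 without lean FBC array 3 and 0.219 under another setting), monocyte markers (0.057 without lean FB array 4), eosinophil markers (0.192 without lean FB array 4 and 0.141 under another setting), fibroblast markers (0.456 without lean FBC array 4) and mesothelial markers (0.137 without lean FBC array 4 and 0.0612 under another setting). Medians moved by over 1.5 times without the 3 arrays of high actin ratio for the cell cycle list (0.435), the monocyte list (-0.13), the eosinophil list (-0.53) and the ribosomal list (0.045).

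The same 2 populations were compared in obese mice. FBC were higher in Mmp12 (4.25 ± 0.55), Fscn1 (3.27 ± 0.29), Gpnmb (3.25 ± 0.37), and Htr2b (3.02 ± 0.31). Also higher were the glucose transport regulator Tbc1d4 (2.87 ± 0.44), the endoplasmic reticulum protein Wfs1 (2.74 ± 0.28), Ctsk (2.68 ± 0.46) and the coagulation factor F7 (2.60 ± 0.33). They were lower in Cd177 (-4.18 ± 0.42), Vcan (-4.01 ± 0.33), thrombospondin, Thbs1 (-3.86 ± 0.72), and the coagulation factor F5 (-3.85 ± 0.61). Further lower genes were histidine decarboxylase, Hdc (-3.55 ± 0.34), the formyl peptide receptor Fpr2 (-3.44 ± 0.34), Plac8 (-3.42 ± 0.54) and Klra2 (-3.42 ± 0.55). The adjusted p of these 16 genes was at most 0.00341. In all, 999 genes differed, 609 higher and 390 lower, 555 of them by at least 2-fold, and 2988 had an unadjusted p under 0.05.

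Monocyte markers were lower in obese FBC than in obese FB, 11 of 15, with Vcan, Plac8 and Treml4 (-3.35 ± 0.58) lowest. The monocyte list gave a median change of -1.70, adjusted p = 7.82e-17, and adjusted p = 0.0275 with an estimated correlation (0 higher and 12 lower adjusted over the list alone). Neutrophil markers were lower, 9 of 13, with the activating receptor Trem1 (-3.23 ± 0.54), Slfn4 (-2.69 ± 0.35) and the calgranulin S100a9 (-2.68 ± 0.55). The neutrophil list gave a median change of -1.32, adjusted p = 1.69e-09, and adjusted p = 0.176 with an estimated correlation (0 higher and 10 lower adjusted over the list alone). Classic activation genes were lower, 2 higher and 7 lower of 23: Acod1 (-3.20 ± 0.48) and Il6 (-2.04 ± 0.31) were lower and Il12b (2.07 ± 0.49) higher. The classic activation list gave a median change of -0.35, adjusted p = 0.00113, and adjusted p = 0.292 with an estimated correlation (2 higher and 9 lower adjusted over the list alone). Alternative activation genes went both ways, 3 higher and 2 lower of 24, with no call (adjusted p = 0.798, 6 higher and 4 lower adjusted over the list alone), among them Socs2 (2.00 ± 0.22), Ccl22 (2.16 ± 0.36) and Chil3 (-2.88 ± 0.45). The list of 25 interferon-stimulated genes was called lower, with 0 higher and 1 lower past the threshold. The interferon list gave a median change of -0.21, adjusted p = 0.0158, and adjusted p = 0.552 with an estimated correlation (0 higher and 1 lower adjusted over the list alone).

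Lysosome genes were higher in obese FBC than in obese FB, 12 higher and 1 lower of 45, with Atp6v0d2 (2.32 ± 0.35) and cathepsin D, Ctsd (1.66 ± 0.33). The lysosome list gave a median change of 0.56, adjusted p = 7.17e-08, and adjusted p = 0.292 with an estimated correlation (25 higher and 1 lower adjusted over the list alone). Lipid-associated macrophage genes were higher, 10 of 26, with Mmp12 and Gpnmb highest. The lipid-associated macrophage list gave a median change of 0.72, adjusted p = 4.57e-07, and adjusted p = 0.292 with an estimated correlation (13 higher and 0 lower adjusted over the list alone). The lipid uptake list had 8 higher and 4 lower of 29 and no call (adjusted p = 0.475, 10 higher and 4 lower adjusted over the list alone), with Pla2g15 (2.11 ± 0.39) and the monoglyceride lipase Mgll (1.70 ± 0.40) higher and Olr1 (-2.06 ± 0.51) lower. Fatty acid oxidation genes were higher, 6 of 21, with Pdk4 (1.13 ± 0.28), Cpt2 (1.05 ± 0.26) and Acaa2 (0.97 ± 0.28). The fatty acid oxidation list gave a median change of 0.41, adjusted p = 0.0158, and adjusted p = 0.292 with an estimated correlation (7 higher and 0 lower adjusted over the list alone). Cell cycle genes were higher, 10 of 30, with Cdk1 (1.5 ± 0.32), Prc1 (1.35 ± 0.33) and Bub1 (1.34 ± 0.25). The cell cycle list gave a median change of 0.84, adjusted p = 7.17e-08, and adjusted p = 0.473 with an estimated correlation (18 higher and 0 lower adjusted over the list alone). The FBC and FB arrays overlapped for S100a9 and Prc1. Dendritic cell markers were higher, 5 of 20, with Fscn1, Ccl22 and Ccr7 (1.99 ± 0.38). The dendritic cell list gave a median change of 0.43, adjusted p = 0.0156, and adjusted p = 0.473 with an estimated correlation (7 higher and 0 lower adjusted over the list alone).

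Perivascular macrophage genes were higher in obese FBC, 3 of 23, with Fcna (2.14 ± 0.56), the scavenger receptor Marco (1.93 ± 0.42) and the complement receptor Vsig4 (1.83 ± 0.41). The perivascular list gave a median change of 1.20, adjusted p = 0.000903, and adjusted p = 0.725 with an estimated correlation (3 higher and 0 lower adjusted over the list alone). Fibroblast markers were higher alongside, 1 of 20, with scores of -0.85 ± 0.07 in obese FB and -0.04 ± 0.79 in obese FBC. The fibroblast list gave a median change of 0.84, adjusted p = 0.022, and adjusted p = 0.754 with an estimated correlation (0 higher and 0 lower adjusted over the list alone). The list of 13 complement genes was called higher, though by limma no single gene passed the threshold. The complement list gave a median change of 0.74, adjusted p = 0.0158, and adjusted p = 0.725 with an estimated correlation (0 higher and 0 lower adjusted over the list alone). The list of 19 endothelial markers was called higher, though by limma no single gene passed the threshold. The endothelial list gave a median change of 0.75, adjusted p = 0.0158, and adjusted p = 0.725 with an estimated correlation (0 higher and 0 lower adjusted over the list alone).

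The obese FBC to FB count was 1655 with the replicate number as a block, 1746 with mouse as a random block, 906 higher and 317 lower with median centring, 2202 with array weights, 652 and 606 without obese FB arrays 2 and 4, and 553 without obese FBC array 2. Gene calls ended on leaving out 1 array, with the highest adjusted p each reached, without obese FB array 4 those of Prc1 (0.0698), without obese FBC array 2 those of Acaa2 (0.146), Cpt2 (0.069), Fcna (0.0944) and Olr1 (0.0736), without obese FBC array 3 those of Mgll (0.0519) and Pdk4 (0.0574), and other settings ended those of Prc1, Bub1, Mgll, Olr1, Il12b, Socs2, Fcna, Cpt2 and Acaa2 (adjusted p 0.0502 to 0.539). List calls ended, with their highest adjusted p, for interferon-stimulated genes (0.0619 without obese FBC array 3 and 0.0592 under another setting), fibroblast markers (0.231 without obese FBC array 3 and 0.502 under another setting), endothelial markers (0.0977 without obese FBC array 3 and 0.0994 under another setting), fatty acid oxidation (0.0722 under another setting), perivascular genes (0.128 under another setting), complement (0.428 under another setting) and dendritic cell markers (0.0548 under another setting). Medians moved by over 1.5 times without the 3 arrays of high actin ratio for the classic activation list (-0.205) and the complement list (0.485). Between the FBC to FB differences of lean and obese mice, 14 genes were higher and 3 lower in both, against 0.9 and 0.2 for independent lists, and the changes correlated at r = 0.243 across genes.

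Whether obesity acted differently on FBC and FB was tested as an interaction. The obesity effect was more positive in FBC for Rusc2 (3.61 ± 0.65), Lims2 (2.93 ± 0.55), the desmosomal gene Pkp2 (2.80 ± 0.38), Htr2b (2.68 ± 0.43), Mfge8 (2.19 ± 0.41) and the scavenger receptor Stab2 (1.08 ± 0.20). It was more negative in FBC for the cytokine Lif (-2.72 ± 0.31), the phospholipase Plcb1 (-2.57 ± 0.48), the cystine transporter Slc7a11 (-2.57 ± 0.45), the ephrin Efnb2 (-2.15 ± 0.38) and Ear3 (-1.94 ± 0.30), a ribonuclease of a multigene family. The adjusted p of these 11 genes was between 0.00155 and 0.0457. Mfge8 was at 8.52 ± 0.37 and 8.49 ± 0.46 in lean and obese FB and at 8.33 ± 0.30 and 10.48 ± 0.59 in lean and obese FBC. In all, 19 genes passed, 10 higher and 9 lower, and 1576 had an unadjusted p under 0.05.

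Lists were tested for the same difference. The list of 45 lysosome genes had a more positive obesity effect in FBC, though by limma no single gene passed the threshold. The lysosome list gave a median change of 0.53, adjusted p = 1.15e-06, and adjusted p = 0.436 with an estimated correlation (1 higher and 0 lower adjusted over the list alone). The list of 26 lipid-associated macrophage genes had a more positive obesity effect in FBC, though by limma no single gene passed the threshold, and the sign of its camera test turned without quantile normalization (median 0.18, adjusted p = 0.725) and with median centring (0.05, adjusted p = 0.795). The lipid-associated macrophage list gave a median change of 0.50, adjusted p = 0.0362, and adjusted p = 0.77 with an estimated correlation (0 higher and 0 lower adjusted over the list alone). The list of 24 phagocytosis receptors had a more positive obesity effect in FBC, with 2 higher and 0 lower past the threshold. The phagocytosis list gave a median change of 0.53, adjusted p = 0.0362, and adjusted p = 0.436 with an estimated correlation (3 higher and 0 lower adjusted over the list alone). The list of 23 perivascular macrophage genes had a more positive obesity effect in FBC, though by limma no single gene passed the threshold. The perivascular list gave a median change of 1.47, adjusted p = 0.000101, and adjusted p = 0.77 with an estimated correlation (0 higher and 0 lower adjusted over the list alone). The list of 13 complement genes had a more positive obesity effect in FBC, though by limma no single gene passed the threshold. The complement list gave a median change of 1.02, adjusted p = 0.00117, and adjusted p = 0.737 with an estimated correlation (0 higher and 0 lower adjusted over the list alone). The list of 20 fibroblast markers had a more positive obesity effect in FBC, though by limma no single gene passed the threshold. The fibroblast list gave a median change of 1.44, adjusted p = 7.52e-05, and adjusted p = 0.77 with an estimated correlation (0 higher and 0 lower adjusted over the list alone). The list of 19 endothelial markers had a more positive obesity effect in FBC, though by limma no single gene passed the threshold. The endothelial list gave a median change of 0.78, adjusted p = 0.0314, and adjusted p = 0.77 with an estimated correlation (0 higher and 0 lower adjusted over the list alone).

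Further lists went the other way. The list of 15 monocyte markers had a more negative obesity effect in FBC, though by limma no single gene passed the threshold. The monocyte list gave a median change of -1.17, adjusted p = 2.94e-10, and adjusted p = 0.159 with an estimated correlation (0 higher and 8 lower adjusted over the list alone). The list of 23 classic activation genes had a more negative obesity effect in FBC, though by limma no single gene passed the threshold. The classic activation list gave a median change of -0.35, adjusted p = 0.000207, and adjusted p = 0.436 with an estimated correlation (1 higher and 6 lower adjusted over the list alone). The list of 34 oxidative phosphorylation genes had a more negative obesity effect in FBC, though by limma no single gene passed the threshold. The oxidative phosphorylation list gave a median change of -0.21, adjusted p = 0.0362, and adjusted p = 0.77 with an estimated correlation (0 higher and 0 lower adjusted over the list alone). The list of 23 ribosomal protein genes had a more negative obesity effect in FBC, though by limma no single gene passed the threshold. The ribosomal list gave a median change of -0.12, adjusted p = 0.00669, and adjusted p = 0.607 with an estimated correlation (0 higher and 0 lower adjusted over the list alone). The alternative activation and lipid uptake lists were not called (adjusted p = 0.703 and 0.686).

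The interaction count was 230 with the replicate number as a block, 158 with mouse as a random block, 3 without the filter (1 higher and 2 lower), 9 with probe sets singly (4 and 5), 4 with a pseudocount of 1 and 30 with trend and robust settings. It was 349 without lean FB array 4, 62 without obese FB array 1 (22 higher and 40 lower), 298 without the 3 arrays of high actin ratio, 1536 with array weights, 18 higher and 8 lower without quantile normalization, 11 and 6 with median centring and 12 and 7 with cyclic loess, and between 2 and 8 on leaving out any other single array but lean FBC array 3. Gene calls ended on leaving out 1 array, with the highest adjusted p each reached, without lean FB array 3 those of Efnb2 (0.109), Htr2b (0.0859), Lims2 (0.122), Mfge8 (0.124), Plcb1 (0.122), Rusc2 (0.122), Slc7a11 (0.122) and Stab2 (0.122), without obese FBC array 4 those of Ear3 (0.0583), and other settings ended those of Rusc2, Lims2, Htr2b, Mfge8, Plcb1, Slc7a11, Efnb2 and Stab2 (adjusted p 0.0508 to 0.201). List calls ended, with their highest adjusted p, for lipid-associated genes (0.223 without obese FBC array 1 and 0.795 under another setting), phagocytosis receptors (0.119 without lean FB array 4 and 0.361 under another setting), oxidative phosphorylation (0.177 without lean FBC array 3 and 0.0761 under another setting), endothelial markers (0.162 without lean FBC array 4 and 0.107 under another setting) and lysosome (0.0723 under another setting). Medians moved by over 1.5 times without the 3 arrays of high actin ratio for the lipid-associated macrophage list (0.27), the phagocytosis list (0.25) and the ribosomal list (-0.19).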

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

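The tests on fibroblast list members, on single perivascular genes, on omission of the 3 arrays from the perivascular and monocyte lists, on the position of lean FBC array 4 and on the alternative activation score of lean FB array 4 were chosen after the result was seen; so were the relabellings by number, while the other split tests and the other 4 were written before it.

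An array is named here when it stands apart from the other 3 of its group beyond Dixon's limit, which chance gives in about 1 in 20 groups; of 329 gene and group pairs 39 stood apart, against 16.4 by chance, of 136 list scores 14, against 6.8, and of 4 actin ratios 3, against 0.2. Lean FB array 1 was the lowest for Rusc2 (5.55). Lean FB array 2 was the lowest for Bub1 (5.49). Lean FB array 4 was the lowest for Cpe (7.13), Cd209g (8.80), Sult1e1 (7.66), Klhl13 (7.45), Car3 (10.65), Cd209f (9.42), Cd209b (7.99), Dcn (10.56), Oasl1 (7.74), Atp6v1h (10.04), Vldlr (6.27), Cxcl12 (9.21), Mmp12 (5.54) and Lims2 (5.97) and the highest for Rnf128 (8.23), Cd177 (8.61), Treml4 (11.37), Slfn4 (11.15) and Plcb1 (9.55). Lean FBC array 3 was the highest for Gpnmb (10.07). Lean FBC array 4 was the lowest for Pla2g2d (8.21), Sult1e1 (6.83), Car3 (10.12), Cd209f (8.62) and Adgre1 (11.94) and the highest for Fscn1 (12.76). Obese FB array 1 was the lowest for Vcan (9.52), Fpr2 (11.62) and Acod1 (8.43) and the highest for Ces1d (5.43), Bub1 (6.69) and Marco (4.49). Obese FB array 3 was the lowest for Cxcl13 (4.22). Obese FB array 4 was the lowest for Klhl13 (4.41) and the highest for Upk3b (5.51). Obese FBC array 3 was the lowest for Ccl24 (5.87) and Wfs1 (10.53). Among list scores, lean FB array 4 for perivascular genes (-0.492, lowest), iron and haem handling (-0.418, lowest), monocyte markers (0.914, highest), eosinophil markers (3.27, highest), adipocyte markers (-0.317, lowest) and fibroblast markers (-0.717, lowest); lean FBC array 4 for perivascular genes (-1.229, lowest), phagocytosis receptors (-0.507, lowest), cell cycle (0.618, highest), extracellular matrix and matrix remodelling (-0.679, lowest), monocyte markers (-0.085, highest) and fibroblast markers (-1.218, lowest); obese FB array 1 for adipocyte markers (-0.695, lowest); obese FB array 4 for pan-macrophage markers (-0.406, lowest) stood apart. The actin ratio was 53.3, 48.0 and 45.0 on arrays 4 of lean FB, lean FBC and obese FB.

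The obesity effect differed between FBC and FB, by the interaction test, for Rusc2 (3.61), Lims2 (2.93), Pkp2 (2.80), Htr2b (2.68), Mfge8 (2.19), Lif (-2.72), Plcb1 (-2.57), Slc7a11 (-2.57), Efnb2 (-2.15), Ear3 (-1.94) and Stab2 (1.08). The lists with such a difference, by median, were lysosome (0.526), classic (M1) activation (-0.347), lipid-associated genes (0.501), perivascular genes (1.466), complement (1.022), phagocytosis receptors (0.527), oxidative phosphorylation (-0.212), ribosomal proteins (-0.118), monocyte markers (-1.172), fibroblast markers (1.435) and endothelial markers (0.782).

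Fibroblast and perivascular macrophage genes were lower together in obese FB. For the first, fibroblast RNA carried into the lean cells, which the sort gates would reduce, cannot be told from a difference between genotypes. Both predict the median of -1.846 outside the 5 most abundant members. Within genotypes the members varied together (mean correlation 0.186 over 6 FB arrays without high actin ratio). That was more than random gene sets (share as high 0.01, median 0.001) but less than lipid-associated (0.371) and perivascular genes (0.331). With the fibroblast score as a covariate the median of 22 perivascular genes went from -1.489 to -0.111 (adjusted p = 0.254). Arrays 4 of lean FB and lean FBC, lowest of their groups for both lists, may drive this fit, so it leaves carried RNA open. Carried RNA is less able to explain all called genes: with the covariate 4 of 8 were still called lower, just at the bound set. Among them were Cd209g (-3.65 ± 0.41) and Timd4 (-2.83 ± 0.47). Degraded RNA in the 3 arrays is argued against by a perivascular median of -1.293 without them, against -1.268 with them, and a difference between genotypes stays open.

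Monocyte markers were lower in obese FBC than in obese FB, together with neutrophil markers. Neutrophil RNA, which the macrophage antigen gate would reduce, was tested with the neutrophil score as a covariate: the monocyte median went from -1.696 to -1.323 and stayed called (adjusted p = 1.1e-07), which argues against it as the whole cause; S100a9 averaged 8.01 in obese FB and 5.34 in obese FBC. Without the 3 arrays of high actin ratio the median was -1.84 (adjusted p = 3.2e-19), which argues against degraded RNA in those arrays as the cause. Obese FBC array 3, with a Gapdh ratio of 28.1, was kept. Monocytes inside the FB gate, and a difference between the populations themselves, stay open and may both apply; neither was tested.

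The FB count rose from 701 to 2022 without the 3 arrays of high actin ratio. Fewer arrays alone is argued against, since 1 of the 64 ways to leave out 1 array from each of the 3 groups gave as many genes, this one (highest other 1981, median 315). Leaving out lean FBC array 4 and obese FB array 4 gave 1054, just over 1.5 times the count, and lean FB array 4 alone 1501, so degraded RNA may contribute and much of the rise goes with lean FB array 4. An obese array labelled lean is argued against for lean FBC array 4, which lay 0.244 of the way from lean to obese mean. In lean FB array 4 the alternative activation score (0.423) lay among the other lean (0.42 to 0.526), not the obese arrays (-0.667 to -0.481). Its monocyte (0.914) and complement scores lay in the obese range. Over all genes called without both arrays it lay at 0.687, outside the other lean (-0.012 to 0.06) and obese arrays (0.931 to 1.044). So this label stays open, as do eosinophils (Siglecf 11.98), which can carry the macrophage antigen and CD11b, and any biological explanation, untested.

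Other splits of the arrays were counted. The real split alone of 35 gave as many genes: FB 701 (highest other 195), FBC 1675 (0), lean 23 (5) and obese 999 (1). So chance is excluded at 1 in 20 for FB and FBC, unless equal numbers mark a shared preparation. In lean and obese mice they may pair FB and FBC arrays. The labels state neither. In either case the 8 splits that part all 4 numbers are too few for a share under 0.05. Highest others were then 108 in FB, 0 in FBC and lean and 1 in obese mice. For the interaction, genotype was relabelled within FB and within FBC apart, which ignores any pairing by number. Of 100 labellings, the real one among them, 4 gave 19 genes or more, and the highest other gave 166. Such a draw can leave the obesity effect of 1 population in the difference, so these counts do not decide on chance. With the FB and FBC arrays of a number relabelled together, the real split was the 1 of 35 with as many genes (19, highest other 0). Every other such split mixes lean and obese arrays in a group, so the obesity effect widens the spread and low counts follow. This share is therefore no support for the 19 genes. The fits with a block gave 230 and 158 genes.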

How the results depend on the processing

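The actin covariate and the omission of the 3 arrays of high actin ratio were chosen after the result was seen; the other settings were planned. Over all settings, named gene calls were the same 3852 times, ended 392 times, were gained 6 times and reversed 0 times, and list calls were the same 1546 times, ended 207 times and reversed 2 times. Both reversals were in the interaction of lipid-associated macrophage genes, with medians of 0.177 without quantile normalization and 0.053 with median centring, where the sign of the camera test turned; the cause was not tested. The median of all genes shifted by over 0.1 without quantile normalization (0.119 in FBC, 0.135 in obese FBC against FB, 0.171 in the interaction) and with median centring (0.128 in obese FBC against FB), and changes under those scalings are read relative to it.

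Gene counts moved beyond 1.5 times with array weights, to 3987 in FB, 4115 in FBC, 1324 in lean and 2202 in obese FBC against FB, 1536 in the interaction and 1704 shared by FB and FBC, with weights from 0.249 (lean FB array 4) to 6.541 (lean FBC array 2). The 2-fold minimum, by construction, gave 811 in FBC, 555 in obese FBC against FB and 213 shared. The lean count was 37 with the stricter filter, 42 with median centring, 9 with only the groups compared, 51 with the replicate block and 74 with the random block. The obese FBC to FB count was 1655 and 1746 with the blocks. The interaction count was 3 without the filter, 9 with probe sets singly, 4 with a pseudocount of 1, 30 with trend and robust settings, and 230 and 158 with the blocks. The actin covariate gave 1159 in FB, 62 in lean mice and 530 shared. Without the 3 arrays the counts were 2022 in FB, 15 in lean mice, 298 in the interaction and 934 shared; these held 684 of the 701 FB genes, 9 of the 23 lean genes and 19 of the 19 interaction genes. Apart from the 2-fold minimum and the FB count without the 3 arrays, the cause was not tested. The lists called with an estimated correlation numbered 1 in FB, 2 in FBC, 0 in lean mice, 1 in obese mice and 0 in the interaction, and 7 interaction lists were called with cyclic loess and 7 with the actin covariate. Without the 3 arrays, further lists were called in FB (cholesterol, iron and haem, endothelial), FBC (perivascular, fibroblast, adipocyte, neutrophil, immediate early) and the interaction (neutrophil). None held with an estimated correlation.

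On leaving out 1 array, the counts ranged from 333 to 1501 in FB, 1040 to 1553 in FBC, 8 to 25 in lean mice, 553 to 1053 in obese mice, 2 to 349 in the interaction and 209 to 496 shared. Called lists ranged from 21 to 24, 12 to 17, 8 to 15, 10 to 13 and 7 to 11. Adgre1 in obese FBC against FB gained a call with both blocks and with trend and robust settings, and Itgax in FBC gained one with array weights and without the 3 arrays. No value exists for the interaction with only the groups compared, for lists with the random block or the 2-fold minimum, or for other probe sets of the sort markers, which have 1 each. For dim genes, signal close to background limits the size of the change.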

Other observations

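The osteoclast test was chosen after the result was seen. Of the lists called in no comparison, several held members that changed in obese FBC, named here after their values were seen. In glycolysis 3 rose and 1 fell of 16 (adjusted p = 0.808, 4 higher and 3 lower adjusted over the list alone): Pdk1 (1.36 ± 0.25), Ldha (0.92 ± 0.25) and Hk3 (0.67 ± 0.19) rose and Hk2 (-1.49 ± 0.20) fell. In the hypoxia response list 2 rose and 3 fell of 18 (adjusted p = 0.489, 2 higher and 3 lower adjusted over the list alone), with Adm (-2.00 ± 0.35), a vasodilator peptide, and Hif1a (-0.74 ± 0.19) lower. In cholesterol biosynthesis 3 rose and 0 fell of 20 (adjusted p = 0.489, 3 higher and 0 lower adjusted over the list alone), namely Msmo1 (1.09 ± 0.22), Hsd17b7 (1.04 ± 0.32) and Lss (0.55 ± 0.17). Of pan-macrophage markers 4 rose and 1 fell of 17 (adjusted p = 0.365, 5 higher and 1 lower adjusted over the list alone), with Fcgr1 (0.96 ± 0.28) and Sirpa (0.87 ± 0.25) higher and Aif1 (-1.07 ± 0.30) lower. In iron and haem handling 1 rose and 0 fell of 15 (adjusted p = 0.68, 1 higher and 0 lower adjusted over the list alone), namely the biliverdin reductase Blvra (0.96 ± 0.17). The erythroid list had fewer tested genes than the test needs and was not tested.

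Cathepsin K, Atp6v0d2 and Gpnmb, which osteoclasts also make, were among the genes highest in obese FBC. A list of 27 osteoclast genes, of which 3 were these, was written after that was seen, and 21 others were tested. Of these, 9 rose and 2 fell, with a median log2 change of 0.52 (camera p = 0.0014, and p = 0.00633 with an estimated correlation). Acp5 (1.65 ± 0.36), Tcirg1 (1.20 ± 0.17) and Clcn7 (1.26 ± 0.18) rose, and Mmp9 (-2.92 ± 0.47) and Fosl2 (-0.57 ± 0.18) fell. Nfatc1 (0.20), Itgb3 (-0.44) and Ocstamp (-0.13) were not called. An osteoclast-type programme is a candidate for the rise but was not told apart from the lysosome list. That list rose too and holds 2 of the tested genes, and the test used the data that raised it.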
